A study of Homo sapiens with 118 samples.

How the data were processed

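RNA-seq and ATAC-seq were made from human induced pluripotent stem cell lines and from neural progenitor cells and 3 kinds of neuron differentiated from them. The labels describe 118 samples: 55 RNA libraries and 63 ATAC libraries (7 iPSC, 20 NPC, 20 CN, 8 GA and 8 DN). Groups and replicate numbers were read from the sample titles. For 4 RNA and 3 ATAC libraries another label field named another cell type than the title; the title was used, and the RNA comparisons were repeated without those 4. A further 5 RNA libraries are labelled as neural progenitors, but their titles carry the prefix VPS, which points to VPS45, and in 4 of the 5 a name with a letter stands in place of a replicate number. The labels do not say how they differ from the other NPC, so they were put in no group and entered no comparison.

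The RNA values were raw fragment counts per gene, made by the authors with featureCounts 1.6.3 and the GENCODE 28 annotation on hg38, per the file headers. The header's options required both ends to map, left out chimeric fragments and duplicates, kept primary alignments and set no strand, so reads of a gene and of an overlapping or antisense gene cannot be told apart. By RefSeq coordinates, a transcript named after SLC17A6 overlaps the first bases of SLC17A6 as annotated by GENCODE. Closely related genes such as HOX and DLX family members may share reads. STAR 2.6.0, Trimmomatic, SAMtools and Picard are named without a role in the submitters' processing notes, as are Bowtie2 and the builds hg38 and GRCh38.p7. The table held 58381 genes. Genes of the Y chromosome, XIST and TSIX (565 genes) were removed before any step, since the lines come from people. The table had 56 count columns, of which 55 matched a sample and 1 was not used. Total counts per library ran from 7411808 to 14596769, with a median of 10342715. Genes with at least 10 counts numbered 14659 to 15053 in iPSC, 14010 to 14595 in NPC, 14240 to 16683 in CN, 14715 to 16346 in GA and 14890 to 16338 in DN. Mitochondrial genes held 4.32% to 7.91% of counts in iPSC and 2.27% to 4.11% in NPC, without overlap. The shares were 3.03% to 5.67% in CN, 3.18% to 5.92% in GA and 3.54% to 6.38% in DN.

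The open-chromatin lists held positions and a score per entry, deposited by the authors as 1 list per cell type, with no header; the score is the authors' and its scale is not given in the sources used here. The peak caller is not given in the sources used here. The entry names point to calls pooled over the libraries of a cell type, so no replicate error can be had. The lists held autosomes only, with scores from 13 up, and pooled different numbers of libraries. A combined list of 656154 entries was used only to match genes on the density of open chromatin.

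Gene counts were tested with edgeR 4.0.16 (R 4.3.3). Genes passing filterByExpr (17420) were scaled by TMM, and 1 quasi-likelihood model with a mean for each of the 5 cell types was fitted to the 50 grouped libraries. A gene was called where the Benjamini-Hochberg adjusted p lay under 0.05 and the absolute log2 fold change was at least 1. Every adjusted p of a gene is from this test unless an alternative is named. SE is the absolute log2 fold change over the square root of the F statistic. CPM are counts scaled to the library's total over the genes passing the filter times its TMM factor, given as mean ± SD. In GA these factors ran from 0.854 to 1.402, so CPM differ from counts scaled to the plain library total. Where a group had 0 counts, a fold was computed against a floor of 3 counts over the group, and where it had 1 to 3 counts levels are given and no fold. Such floors and intervals cover counting error only. Against the 4243 and 2502 genes called in GA against NPC, 11464 genes had an unadjusted p under 0.05; the numbers for NPC against iPSC, CN against NPC, DN against NPC, GA against CN, DN against CN and DN against GA were 11412, 8213, 11384, 9825, 9443 and 5020.

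Lists of 490 genes in 27 groups, fixed before the data were examined, were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with the correlation estimated per list, adjusted over the lists within a comparison. Of 189 list tests 58 were called, 4 of them also with the estimated correlation and 54 not. The 4 were pluripotency and epithelial and placode in NPC against iPSC, and pluripotency and postsynaptic and ion channels in CN against NPC. Some lists share members, such as FOXA2, ARX and SST. A preset-correlation call lost with the estimated correlation is given with both p.

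The rule for named genes was fixed before the data were examined. It took per comparison the 8 genes with the largest rise and the 8 with the largest fall among called protein-coding genes with a mean of at least 10 CPM and no overlap of the groups, the first 6 members of each list that defines a cell type, the 4 called members of each list with the largest change, and VPS45, with ASCL1 and DLX2 first in comparisons with GA. It gave 215, 205, 209, 223, 212, 206 and 197 genes for the 7 comparisons in the order of the report. The text names 32, 30, 31, 26, 23, 24 and 24 of these, a subset picked after their values were seen. The alternatives were computed for every gene under the rule.

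Same replicate numbers name the same stem cell line, per the labels' design text, so the numbers pair the libraries. Over 74 pairs of same-numbered libraries of different cell types, the correlation of deviations from the group means was 0.176 on average (-0.194 to 0.476) and over 0.1 in 52, against a mean of -0.015 for other numbers, and in 47 the same-numbered library was the best match. The planned model had no block, and the line as a replicate block was an alternative. Correlations between libraries of a group ran from 0.829 to 0.963 in GA and from 0.945 to 0.983 in NPC, and no pair of libraries agreed within sampling noise (lowest chi-square per degree of freedom 6.42).

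Entries were compared with bedtools 2.31.1. An entry was shared where at least 1 bp overlapped, with 95% exact binomial intervals. A promoter entry lay within 1 kb of a gene's start. The start was the outermost end, by strand, of all annotated exons of the gene. It can lie away from the start of the transcript mainly used. Distal entries lay 1 to 50 kb from the start and were counted around called autosomal genes against 10000 random sets of the same size, matched on mean expression in 20 bins and drawn from genes not called, by a two-sided permutation test with 0.0001 as its smallest p, adjusted over all such tests.

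On simulated counts for the 17420 genes with 200 changed genes per comparison, the calls recovered 68% to 86% of genes changed by 1.5 and 90% to 99% of genes changed by 3 on the log2 scale, with 1 to 5 false calls per comparison. The simulated genes were independent, with no effect of line or flowcell. False calls from such effects in the real libraries were thus not measured. For the distal test, sets of 500 genes were drawn at random with their real NPC entries. The test called 20 of 20 sets with 1 added entry per gene and 0 of 20 without. Sets without an added entry were drawn like the random sets of the test. The 0 of 20 thus does not show how often it errs on called genes.

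The alternatives were other scalings, no or a stricter low-count filter, tests with another fold rule, DESeq2 1.42.0, only the 2 compared groups, the replicate block, only the 6 lines found in all groups, and fits without the libraries of conflicting labels or of the other GA code series. For the entries they were the stronger part of each list, equal list sizes, reciprocal overlap of 50%, other windows and a 500 bp gap. After the data were seen, flowcell as a term, fits without the 6 libraries with over 16000 genes detected and without only the 4 of CN and DN among them, lists without entries over 10 kb and equal numbers of entries in the distal test were added. A planned count of sequence motifs was not run, since no genome of the build was at hand.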

Results

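Gene expression and open chromatin were measured in human induced pluripotent stem cells (iPSC) and in 4 cell types made from them. These were neural progenitor cells (NPC), cortical glutamatergic neurons harvested on day 15 (CN), GABAergic neurons harvested on day 28 (GA) and dopaminergic neurons harvested on day 30 (DN), the neurons being made from the progenitors. The GABAergic neurons were made by viral delivery of ASCL1 and DLX2 under doxycycline, with drug selection of transduced cells. The dopaminergic neurons were made with FGF8 and the Hedgehog pathway activators purmorphamine and SAG. RNA was sequenced in 55 libraries, of which 50 were compared: 8 iPSC, 8 NPC, 18 CN, 8 GA and 8 DN. The other 5, labelled as neural progenitors under another title prefix, entered no comparison. Total counts per library ran from 7411808 to 14596769, with a median of 10342715. Open chromatin was measured by ATAC-seq, in which a transposase cuts accessible DNA, in 63 libraries, and was analysed as 1 list of regions per cell type. The stated purpose of the series was to follow chromatin accessibility and transcription during neuronal differentiation.

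**Figure D1:**
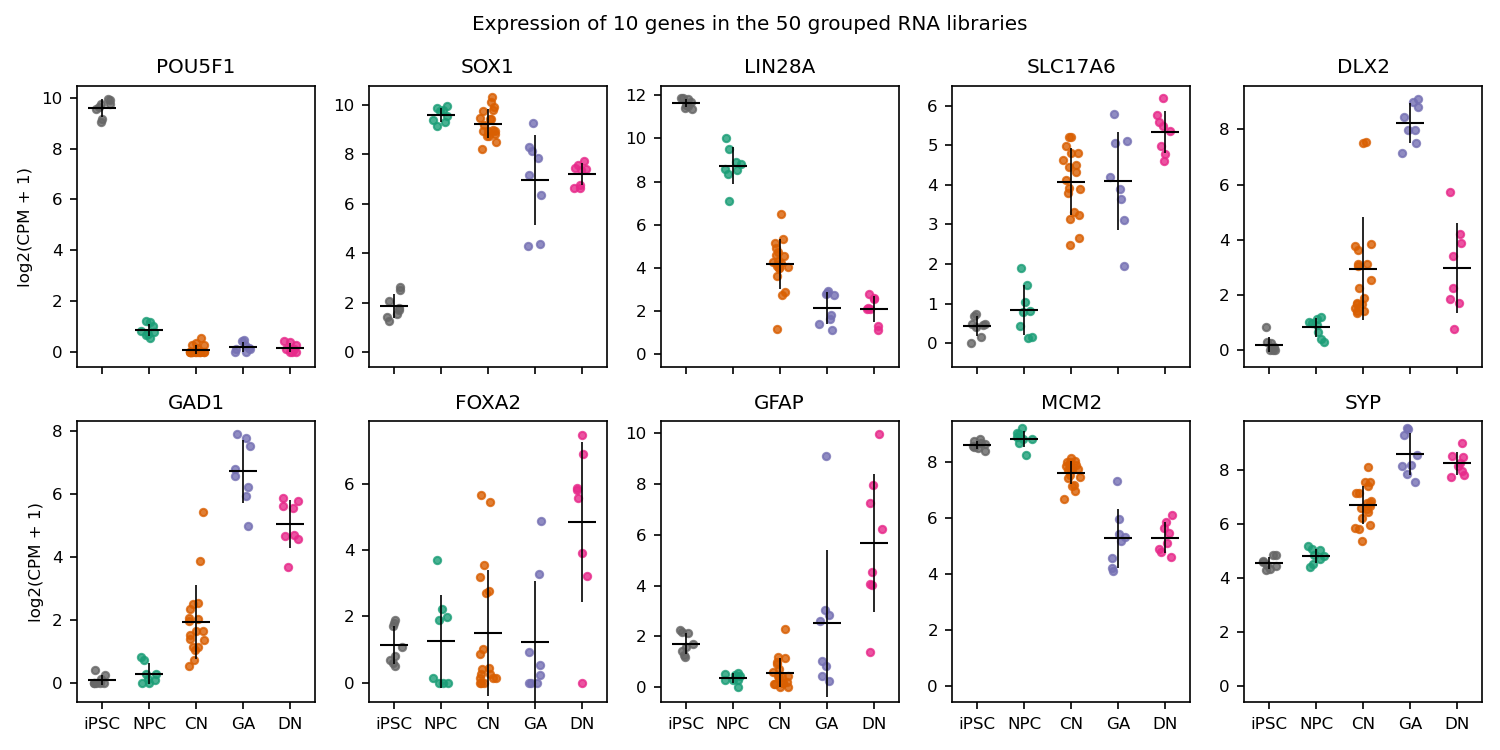
Expression of 10 genes in the 50 grouped RNA libraries, as log2(CPM + 1) on the vertical axis and cell type on the horizontal axis. Points are libraries, horizontal bars are means and vertical bars are 1 SD. POU5F1 lies at a mean of 791 CPM in iPSC and 0.839 CPM in NPC, DLX2 at 333 CPM in GA and 0.819 CPM in NPC, and FOXA2 at 59.7 CPM in DN and 2.68 CPM in NPC.

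The comparison of NPC with iPSC addressed what changed on neural induction. POU5F1 (ENSG00000204531.17, chromosome 6, 31164337 to 31180731), a core pluripotency transcription factor, fell from 791 ± 171 CPM (SD, n = 8) in iPSC to 0.839 ± 0.322 CPM (n = 8) in NPC, a log2 fold change of -9.85 ± 0.40 (SE; adjusted p = 2.08e-26). NANOG, PRDM14 and TDGF1, all linked to pluripotency, fell from 109, 124 and 547 CPM to 0.0663, 0.0896 and 0.439 CPM. LIN28A, an RNA-binding protein that blocks let-7 maturation, fell only in part, from 3205 ± 446 to 486 ± 275 CPM. SOX1 (ENSG00000182968.4, chromosome 13, 112067647 to 112070488), an early neuroectoderm factor, rose from 2.87 ± 1.41 to 789 ± 156 CPM, a log2 fold change of 8.10 ± 0.53 (adjusted p = 1.92e-18). PAX6 rose from 0.656 to 144 CPM and the Notch target HES5 from 0.871 to 649 CPM, while SOX2, which is used in both cell types, was at 985 ± 99.9 CPM in NPC and 1117 ± 156 CPM in iPSC and was not called (log2 fold change -0.18 ± 0.41, adjusted p = 0.715).

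Of the 17420 genes tested, 3603 were higher and 3337 lower in NPC than in iPSC. The pluripotency list had 17 of 19 members lower and 0 higher (adjusted p = 4.84e-21, and 9.42e-08 with an estimated correlation). The epithelial and placode list had 9 of 10 lower (adjusted p = 1.33e-12, and 3.61e-05 with an estimated correlation), among them the epithelial adhesion gene CDH1, from 242 to 0.366 CPM, and the tight junction gene CLDN7, from 152 to 0.0796 CPM. The neural progenitor list had 17 of 22 members higher (adjusted p = 7.45e-10; adjusted p = 0.111 with an estimated correlation). The pan-neuronal list had 20 of 23 higher and 3 lower (adjusted p = 5.16e-12; adjusted p = 0.111 with an estimated correlation), and included STMN2 at 312 ± 101 CPM, DCX at 530 ± 138 CPM and ELAVL3 at 251 ± 57.04 CPM in NPC against 2.51, 8.96 and 3.23 CPM in iPSC. Among the 8 genes with the largest rises were the transcription factors NR2F1, POU3F3 and PRDM8 and the signalling gene WNT7A, at 954, 1474, 211 and 176 CPM in NPC. LCK, a kinase best known from T cells, was among the 8 largest falls, from 82.0 ± 14.7 to 0.0509 ± 0.0548 CPM.

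Genes of the anterior-posterior axis moved in the same comparison. The HOX list, whose members are used in hindbrain and spinal cord, had 14 of 16 members higher in NPC (adjusted p = 0.00466; adjusted p = 0.658 with an estimated correlation). HOXB2 and HOXB3 reached 179 ± 77.0 and 106 ± 68.7 CPM, and HOXB4, with 0 counts in all 8 iPSC libraries, was at 23.01 ± 24.5 CPM in NPC, at least 590-fold higher than the floor of 3 counts over the iPSC group. That mean includes NPC replicate 09 at 78.6 CPM of HOXB4, with the other NPC libraries at or below 28.5 CPM. The midbrain and hindbrain patterning list had 11 of 16 higher and 1 lower (adjusted p = 0.00751; adjusted p = 0.186 with an estimated correlation), with GBX2, a factor of the anterior hindbrain, at 285 ± 57.5 CPM. The forebrain patterning list had 2 of 12 higher and 5 lower and was not called (adjusted p = 0.404). OTX2 fell from 87.5 ± 22.5 to 1.17 ± 2.02 CPM, and EMX1 was at 20.1 CPM in iPSC and 0.0352 CPM in NPC. FOXG1, a telencephalic factor, was below 1 CPM in both. Its call was lost without the libraries with conflicting labels (log2 fold change -3.37 against -3.53, adjusted p = 0.0721), without the low-count filter (-3.52, adjusted p = 0.0552) and in a test against the fold threshold (-3.53, adjusted p = 0.108). The neural crest list moved both ways, with 10 of 17 higher and 5 lower (adjusted p = 0.906): PAX7 rose to 127 ± 38.9 CPM and TFAP2B to 54.4 ± 74.99 CPM, while FOXD3, also used in pluripotent cells, fell from 153 ± 74.3 to 0.450 ± 0.336 CPM. COL3A1, a fibrillar collagen of mesenchyme, was at 68.1 ± 111 CPM in NPC, with replicate 12 at 337 CPM and the others at or below 71.9 CPM.

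The glutamatergic and cortical list had 11 of 20 higher and 2 lower (adjusted p = 0.001; adjusted p = 0.111 with an estimated correlation), and the immediate early and cAMP response list 12 of 23 higher and 2 lower (adjusted p = 0.0361; adjusted p = 0.572 with an estimated correlation). The glycolysis and hypoxia list, with LDHA falling from 327 ± 54.6 to 26.9 ± 3.10 CPM, had 8 of 19 lower and 1 higher (adjusted p = 0.0535, and 0.0231 with the line as a replicate block). The Hedgehog response list had 7 of 13 higher (adjusted p = 0.0727, and 0.0347 with the replicate block). The cell cycle list had 2 of 25 higher and 3 lower (adjusted p = 0.674). Counts adjusted over the list alone equalled those over all genes for each list named for this comparison.

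The comparison of CN with NPC addressed the change over 15 days of differentiation. SLC17A6 (ENSG00000091664.7, chromosome 11, 22338097 to 22379503), a vesicular glutamate transporter, went from 0.951 ± 0.903 CPM (SD, n = 8) to 18.6 ± 9.95 CPM (n = 18), a log2 fold change of 4.27 ± 0.50 (adjusted p = 2.73e-09). The related transporter SLC17A7 stayed below 1.1 CPM in every CN library, and its call (adjusted p = 0.0364) was lost with the replicate block (log2 fold change 1.78 against 1.97, adjusted p = 0.06). SYT13, SHOX2, CBLN2, MAB21L1 and SCN2A were among the 8 largest rises, at 91.8, 33.4, 35.3, 120 and 18.8 CPM in CN. LIN28A fell from 486 ± 275 to 22.5 ± 19.5 CPM, PRTG from 684 to 68.2 CPM, the alkaline phosphatase ALPL from 213 to 26.4 CPM, and the immediate early factors EGR2 and EGR3 from 16.1 and 15.0 CPM to 1.34 and 1.31 CPM.

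In total 1918 genes were higher and 682 lower in CN. The postsynaptic and ion channel list had 21 of 25 higher and 0 lower (adjusted p = 1.45e-16, and 0.0481 with an estimated correlation), with the GABA receptor subunits GABRA2 and GABRG2 rising from 0.108 and 0.144 CPM to 6.21 and 4.93 CPM. The synaptic vesicle list had 17 of 20 higher (adjusted p = 2.89e-14; adjusted p = 0.154 with an estimated correlation), including SYT4, from 44.9 to 400 CPM, and UNC13A, from 15.3 to 94.8 CPM. The pan-neuronal list had 16 of 23 higher (adjusted p = 1.88e-10; adjusted p = 0.154 with an estimated correlation), with the adhesion gene CNTN1 at 12.7 ± 7.02 against 0.651 ± 0.257 CPM. The pluripotency list had 13 of 19 lower and 1 higher (adjusted p = 4.48e-09, and 0.000231 with an estimated correlation). The cell cycle list had 3 of 25 lower (adjusted p = 5.67e-05; adjusted p = 0.68 with an estimated correlation), with the replication factor MCM2 at 201 ± 51.3 against 457 ± 82.8 CPM.

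Some markers of both neurotransmitter classes were called higher in CN. The glutamatergic and cortical list had 9 of 20 higher (adjusted p = 0.0191; adjusted p = 0.356 with an estimated correlation), and the GABAergic and interneuron list 15 of 19 higher (adjusted p = 0.00039; adjusted p = 0.36 with an estimated correlation). SLC32A1, the vesicular GABA transporter, reached 48.9 ± 38.5 CPM. For several of these genes a few libraries carried most of the signal. Those libraries, replicates 04, 10, 17 and 20, came from lines with no NPC RNA library. For their high values line and cell type thus cannot be told apart. DLX2 was at 183 and 181 CPM in CN replicates 04 and 10 and at most 13.6 CPM in the other CN libraries, DLX1 at 187 and 231 CPM there and at most 15.8 CPM elsewhere, and GAD2 at 90.6 and 97.6 CPM there and at most 10.3 CPM elsewhere. GAD1 was highest in replicate 10, at 41.7 CPM. The cortical factors TBR1 and EOMES were at 93.7 and 95.6 CPM in replicate 04, with CN medians of 0.308 and 0.633 CPM, and the forebrain factor SIX3 at 442 and 337 CPM in replicates 04 and 10, with a median of 2.21 CPM. NEUROD2 was called at a mean of 0.831 CPM. FOXG1 reached at most 11.7 CPM and its median was 0. Its call was lost with the replicate block (log2 fold change 0.45 against 4.31, adjusted p = 0.764). EN2, a midbrain and hindbrain factor, was at 310 and 247 CPM in replicates 17 and 20 and at most 4.16 CPM in the others. Its call was lost with only the lines found in all 5 groups (log2 fold change 1.24 against 5.32, adjusted p = 0.157).

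The dopaminergic and midbrain floor plate list (7 of 18 higher, 1 lower, adjusted p = 0.129) and the cholesterol biosynthesis list (1 of 18 higher, adjusted p = 0.097) were called only with the replicate block, at adjusted p = 0.0177 and 0.0382. Adjusted over the list alone, the counts were the same for the lists named for this comparison, except 8 higher in the dopaminergic list. Of the 18 CN libraries, 17 were sequenced on another flowcell than the NPC libraries, so cell type and flowcell were nearly the same split. With flowcell as a term the CN level rests on 1 library. The log2 fold change of SLC17A6 then went from 4.27 ± 0.50 to 4.79 ± 0.735 and of SYT13 from 5.355 ± 0.455 to 4.44 ± 0.61 (± SE). That of LIN28A went from -4.43 ± 0.35 to -4.46 ± 1.30, of DLX2 from 4.91 ± 1.02 to 4.02 ± 1.604, of MCM2 from -1.18 ± 0.23 to -0.97 ± 0.64 and of SYT4 from 3.16 ± 0.38 to 1.74 ± 0.63. The error grew in each, and the change shrank in SYT13, DLX2, MCM2 and SYT4. The change shrank further in GABRG2, from 4.99 ± 0.62 to 1.90 ± 1.32, CBLN2, from 5.19 ± 0.59 to 2.87 ± 0.90, EN2, from 5.32 ± 1.31 to 0.50 ± 2.89, and UNC13A, from 2.63 ± 0.32 to 1.502 ± 0.50, and FOXG1 turned from 4.31 ± 1.38 to -2.68 ± 6.24. FOXG1, MCM2, NEUROD2 and SLC17A7 were not called in a test against the fold threshold.

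GA were compared with NPC to describe the neurons made with ASCL1 and DLX2. ASCL1 (ENSG00000139352.3, chromosome 12, 102957686 to 102960516) was at 548 ± 290 CPM in GA (SD, n = 8) and 78.5 ± 11.6 CPM in NPC (n = 8), a log2 fold change of 2.80 ± 0.26 (adjusted p = 4.54e-13). DLX2 (ENSG00000115844.10, chromosome 2, 172099439 to 172102900) was at 333 ± 153 against 0.819 ± 0.390 CPM, a log2 fold change of 8.64 ± 1.19 (adjusted p = 2.14e-08). Both were delivered by virus, so their counts may include transgene transcripts. DLX1 and DLX5, which were not delivered, rose from 0.347 and 0.0553 CPM to 218 and 29.6 CPM, and DLX6 was at 42.4 CPM with 1 count over the 8 NPC libraries. GAD1 and GAD2, the enzymes that make GABA, rose from 0.268 and 2.40 CPM to 125 ± 76.4 and 127 ± 61.1 CPM, and SLC32A1 from 1.49 to 315 ± 233 CPM.

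GA had 4243 genes higher and 2502 lower than NPC. The GABAergic and interneuron list had 15 of 19 higher and 1 lower (adjusted p = 0.000114; adjusted p = 0.277 with an estimated correlation). The postsynaptic and ion channel list had 24 of 25 higher (adjusted p = 2.36e-14; adjusted p = 0.207 with an estimated correlation), with GABRA2 at 40.8 ± 19.5 CPM and the sodium channel SCN1A at 7.88 ± 5.67 CPM. The synaptic vesicle list had 19 of 20 higher (adjusted p = 3.97e-13; adjusted p = 0.236 with an estimated correlation), with SYP rising from 27.6 to 430 CPM, and the vesicle protein gene SYNPR, outside that list, was at 12.1 CPM with 1 count in NPC. The pan-neuronal list had 19 of 23 higher (adjusted p = 4.2e-07; adjusted p = 0.277 with an estimated correlation), including CNTN1 at 95.7 CPM and RBFOX3 at 80.3 CPM. The cell cycle list had 24 of 25 lower (adjusted p = 6.67e-12; adjusted p = 0.277 with an estimated correlation): MCM2, PLK1 and CDC20 fell from 457, 184 and 269 CPM to 48.8, 22.5 and 33 CPM. The neural progenitor list had 15 of 22 lower and 1 higher (adjusted p = 1.32e-05; adjusted p = 0.277 with an estimated correlation), with HES5 and SOX3 falling from 649 and 2470 CPM to 18.4 and 101 CPM. The pluripotency list had 13 of 19 lower and 4 higher (adjusted p = 0.00634; adjusted p = 0.236 with an estimated correlation), with LIN28A and SALL4 at 3.97 and 8.08 CPM in GA.

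Some marker genes of other cell types were called higher in GA, while the mesenchymal, astrocyte and dopaminergic lists that hold them were not called in the planned fit. GA were kept in medium conditioned by rat astrocytes, with the mitosis inhibitor Ara-C added where other cells than neurons were seen. The mesenchymal and fibroblast list had 12 of 19 higher (adjusted p = 0.0544, and 0.0167 with the replicate block), with the collagen gene COL1A1 at 1224 ± 1212 CPM in GA and 118 ± 248 CPM in NPC, and POSTN at 8.05 against 0.0988 CPM. For COL1A1, NPC replicate 12 was at 728 CPM and the other NPC libraries at or below 65.8 CPM. The astrocyte list had 10 of 16 higher and 3 lower (adjusted p = 0.798), with GFAP at 551 CPM in replicate 05 and at most 7.20 CPM in the other GA libraries. The dopaminergic and midbrain floor plate list had 11 of 18 higher (adjusted p = 0.055, and 0.0167 with the replicate block), including TH, the rate-limiting enzyme of dopamine synthesis, at 70.3 ± 64.3 against 3.11 ± 2.10 CPM. The neuropeptide genes SST and VGF rose from 2.81 and 115 CPM to 114 ± 143 and 3679 ± 3878 CPM.

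The HOX list had 7 of 16 members higher and 1 lower in GA than in NPC (adjusted p = 0.746). HOXA5 rose from 0.320 to 89.1 ± 171 CPM and HOXB5 from 1.16 to 96.8 ± 174 CPM. HOXB8 was at 113 ± 281 CPM, and its call was lost with the replicate block (log2 fold change 1.74 against 4.30, adjusted p = 0.227). The 3 GA libraries of another code series, sequenced on other flowcells, held 16.9 to 805 CPM of HOXB8 and 17.4 to 444 CPM of HOXB5, against 0 to 7.04 and 0 to 10.1 CPM in the other 5. Without them HOXB8 was lower in GA (log2 fold change -1.30, adjusted p = 0.455), HOXB5 was no longer called (log2 fold change 1.30 against 6.35, adjusted p = 0.413). HOXA5 was still called, at a log2 fold change of 3.64 against 8.05 (adjusted p = 0.00116). HOXA5 was at 5.80 to 469 CPM in those 3 libraries and 0.852 to 7.57 CPM in the other 5. Most of its higher mean thus rests on the 3. Adjusted over the list alone, the GABAergic list had 16 higher, the neural progenitor list 2 higher, and the other lists named for this comparison the same counts.

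DN were compared with NPC to describe the dopaminergic protocol. FOXA2 (ENSG00000125798.14, chromosome 20, 22581005 to 22585455), a floor plate factor, rose from 2.68 ± 4.06 CPM (SD, n = 8) to 59.7 ± 60.8 CPM (n = 8), a log2 fold change of 4.47 ± 1.33 (adjusted p = 0.00326), with 0 CPM in DN replicate 12. FOXA1 rose from 9.15 to 192 ± 147 CPM and SHH, the floor plate signal, from 12.5 to 322 ± 236 CPM. The midbrain factor EN1 rose from 1.41 to 30.8 ± 27.9 CPM, and NR4A2, a factor of dopaminergic neurons, from 0.460 to 12.4 ± 7.39 CPM. TH rose from 3.11 to 20.2 ± 7.04 CPM, a log2 fold change of 2.69 ± 0.61 (adjusted p = 0.000159). SPON1, a floor plate matrix protein gene, rose from 5.26 to 1596 ± 1368 CPM. GLI1, a Hedgehog target, fell from 18.8 ± 5.42 to 0.489 ± 0.412 CPM.

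DN had 3996 genes higher and 2561 lower than NPC. The dopaminergic and midbrain floor plate list had 10 of 18 higher and 0 lower (adjusted p = 0.0991, and 0.0325 with the replicate block). The Hedgehog response and ventral neural tube list had 7 of 13 higher and 3 lower (adjusted p = 0.932). The astrocyte list had 12 of 16 higher and 1 lower (adjusted p = 0.0371; adjusted p = 0.623 with an estimated correlation): GFAP was at 190 ± 334 CPM in DN and 0.292 CPM in NPC, S100B at 60.7 against 0.483 CPM, and AQP4 at 17.2 against 0.278 CPM, with replicate 12 highest at 989 CPM of GFAP and 104 CPM of AQP4. Among the 8 largest rises were PMP2, a fatty acid binding protein gene, at 80.6 ± 49.03 CPM, the growth factor gene FGF1 at 49.1 ± 33.9 CPM with 3 counts over the NPC libraries, and FEV, a factor of serotonergic neurons, at 13.5 ± 14.2 CPM. FEV had 0 counts in NPC and was at least 342-fold higher than the floor of 3 counts over that group.

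The postsynaptic and ion channel list had 24 of 25 higher in DN (adjusted p = 1.97e-13; adjusted p = 0.154 with an estimated correlation), with the glutamate receptor subunit GRIN1 rising from 5.10 to 245 ± 102 CPM and SCN1A at 9.90 ± 6.84 CPM. The synaptic vesicle list had 17 of 20 higher (adjusted p = 6.11e-12; adjusted p = 0.282 with an estimated correlation), with SV2B from 0.0945 to 15.3 CPM, and the pan-neuronal list 15 of 23 higher (adjusted p = 4.59e-05; adjusted p = 0.45 with an estimated correlation). The cell cycle list had 24 of 25 lower (adjusted p = 4.86e-13; adjusted p = 0.408 with an estimated correlation), with CDC20 and AURKB at 19.1 and 3.81 CPM in DN against 269 and 65.4 CPM. The neural progenitor list had 13 of 22 lower and 3 higher (adjusted p = 0.00726; adjusted p = 0.623 with an estimated correlation), and HES5 fell to 21.6 CPM. The pluripotency list had 12 of 19 lower and 3 higher (adjusted p = 0.00289; adjusted p = 0.154 with an estimated correlation). LIN28A, FGF19 and NEUROG3 were among the 8 largest falls, to 3.57, 0.191 and 0.189 CPM. The GABAergic list had 13 of 19 higher and 4 lower (adjusted p = 0.0668, and 0.014 with the replicate block), with SLC32A1 at 132 ± 60.2 CPM and GAD1 at 36.1 ± 16.9 CPM. Adjusted over the list alone, the pluripotency list had 13 lower, the Hedgehog list 8 higher, and the other lists named for this comparison the same counts.

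**Figure D2:**
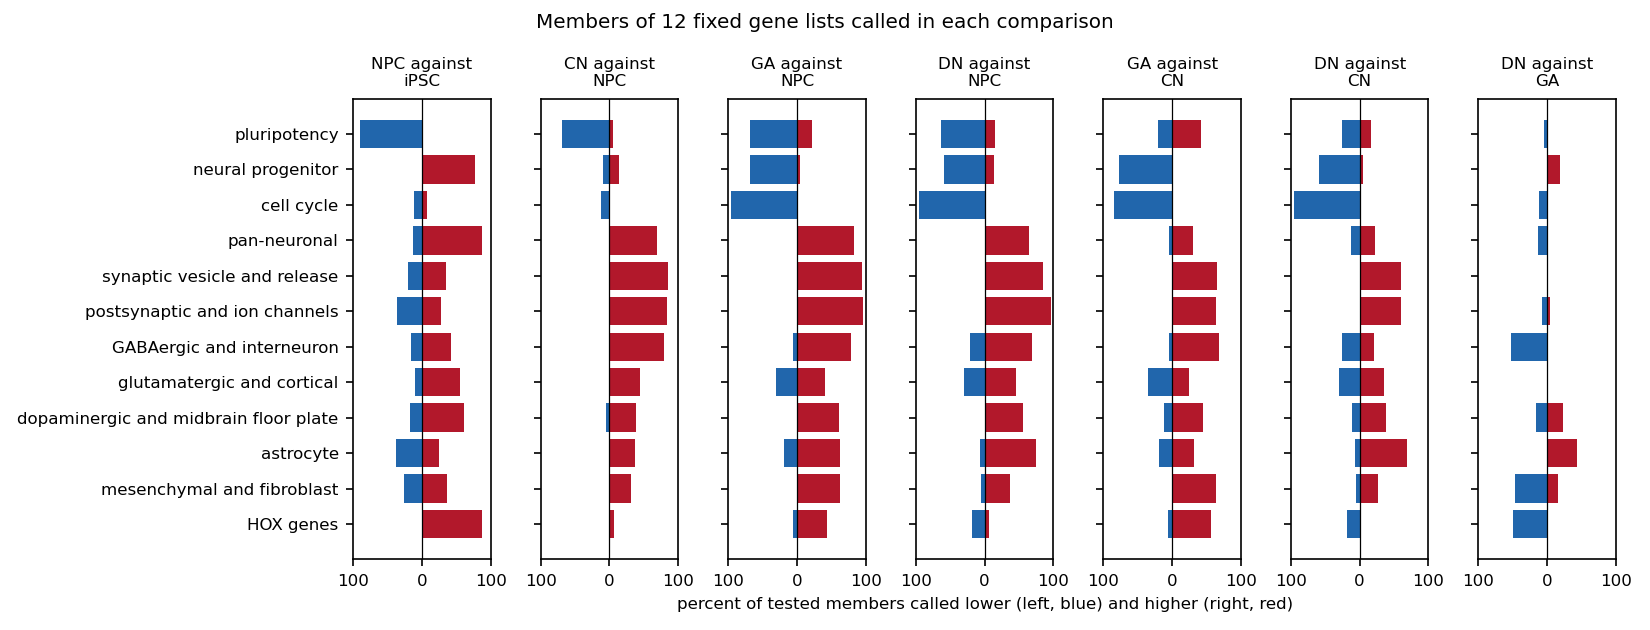
Percent of the tested members of 12 fixed gene lists that were called higher (red, to the right of 0) or lower (blue, to the left of 0) in the cell type named before "against", for the 7 comparisons. The cell cycle list has 24 of 25 members lower in GA and in DN than in NPC, and 3 of 25 lower in CN than in NPC.

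GA and CN were compared to ask how the neuron types differed. CN were harvested on day 15 and GA on day 28, each by its own protocol. Neuron type thus cannot be told apart from time in culture and protocol. ASCL1 and DLX2 were higher in GA, at 548 ± 290 against 135 ± 39.5 CPM and 333 ± 153 against 25.0 ± 57.3 CPM (n = 8 and 18; adjusted p = 1.33e-11 and 8.42e-06). GAD1 (125 against 5.13 CPM), GAD2 (127 against 16.3 CPM) and DLX6 (42.4 against 2.50 CPM) were higher too, and the GABAergic list had 13 of 19 higher and 1 lower (adjusted p = 0.000119; adjusted p = 0.294 with an estimated correlation). The progenitor genes HES5 and SOX3 were lower in GA, at 18.4 and 101 CPM against 283 and 1341 CPM, as were the proneural factors NEUROG1, NEUROG2 and NEUROD4, at 2.02, 8.65 and 5.03 CPM against 45.97, 114 and 46.7 CPM. The muscle intermediate filament gene DES and the potassium channel genes KCNC2 and KCNJ5 were among the 8 largest rises, at 18.7, 12.8 and 13.3 CPM in GA.

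Of all genes, 2662 were higher and 1240 lower in GA than in CN. The neural progenitor list had 17 of 22 lower (adjusted p = 4.34e-11; adjusted p = 0.195 with an estimated correlation), and the cell cycle list 21 of 25 lower (adjusted p = 2.86e-13; adjusted p = 0.294 with an estimated correlation), with CDC20 at 33 against 169 CPM. The postsynaptic list had 16 of 25 higher (adjusted p = 1.71e-09; adjusted p = 0.294 with an estimated correlation), with the calcium channel CACNA1A at 54.2 against 5.81 CPM. The synaptic vesicle list had 13 of 20 higher (adjusted p = 2.27e-08; adjusted p = 0.3 with an estimated correlation), with SYN2 at 62.1 against 6.53 CPM, and the pan-neuronal list 7 of 23 higher and 1 lower (adjusted p = 0.00505; adjusted p = 0.588 with an estimated correlation). The immediate early and cAMP response list had 13 of 23 higher (adjusted p = 0.00162; adjusted p = 0.306 with an estimated correlation), including the activity-regulated genes NPAS4, at 4.85 against 0.209 CPM, and BDNF, at 18.2 against 2.70 CPM. The cholesterol biosynthesis list had 4 of 18 lower (adjusted p = 6.64e-05; adjusted p = 0.314 with an estimated correlation), and the Hedgehog list 6 of 13 lower (adjusted p = 0.0447; adjusted p = 0.588 with an estimated correlation). The glutamatergic and cortical list had 5 of 20 higher and 7 lower (adjusted p = 0.122, and 0.0427 with the replicate block).

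The mesenchymal list had 12 of 19 higher in GA than in CN (adjusted p = 0.00961; adjusted p = 0.588 with an estimated correlation), with COL1A1 at 1224 against 248 CPM, and the epithelial and placode list 6 of 10 higher (adjusted p = 0.0115; adjusted p = 0.294 with an estimated correlation). TH was at 70.3 against 6.51 CPM. HOXB5 and HOXB8 were at 96.8 and 113 CPM against 1.13 and 2.85 CPM. Without the 3 GA libraries of the other code series HOXB5 was not called (log2 fold change 1.32 against 6.41, adjusted p = 0.346), and HOXB8 had a log2 fold change of -0.32 against 5.31 (adjusted p = 0.857). Counts adjusted over the list alone were the same for the lists named for this comparison. All CN libraries but 1 were on a flowcell that held no other cell type. With flowcell as a term the CN level thus rests on 1 library, and the GA level on the GA libraries outside the other code series. The log2 fold change of ASCL1 then went from 2.02 ± 0.19 to 1.31 ± 0.50, of DLX2 from 3.73 ± 0.67 to 4.33 ± 2.51 and of TH from 3.43 ± 0.45 to 2.14 ± 1.18 (± SE). COL1A1 was not called in a test against the fold threshold (log2 fold change 2.31, unchanged; adjusted p = 0.0938).

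Genes of glia and of the floor plate were among those higher in DN than in CN. DN were harvested on day 30 and CN on day 15, each by its own protocol, so cell type cannot be told apart from these. GFAP was at 190 ± 334 CPM in DN (n = 8) and 0.623 ± 0.902 CPM in CN (n = 18), a log2 fold change of 8.23 ± 0.92 (adjusted p = 4.87e-10), AQP4 at 17.2 against 0.617 CPM and S100B at 60.7 against 5.23 CPM. PMP2, the monoamine oxidase gene MAOB, TFPI2 and CPXM2 were among the 8 largest rises, at 80.6, 26.2, 206 and 22.3 CPM in DN. FOXA2, SHH and EN1 were higher, at 59.7, 322 and 30.8 CPM against 6.95, 59.6 and 7.52 CPM, and GLI1 was lower, at 0.489 against 10.1 CPM. NEUROG1, NEUROD4, SOX3 and SALL4 were lower, at 2.06, 2.66, 85.6 and 5.11 CPM against 45.97, 46.7, 1341 and 86.4 CPM. TH was at 20.2 ± 7.04 against 6.51 ± 6.10 CPM (log2 fold change 1.63 ± 0.46, adjusted p = 0.00267). The call of FOXA2 and of SHH was lost with only the lines found in all 5 groups (log2 fold changes 2.32 against 3.10 and 1.99 against 2.44, adjusted p = 0.128 and 0.106).

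The count was 2275 genes higher and 1305 lower in DN. The astrocyte list had 11 of 16 higher and 1 lower (adjusted p = 0.00574; adjusted p = 0.565 with an estimated correlation). The postsynaptic list had 15 of 25 higher (adjusted p = 1.94e-07) and the synaptic vesicle list 12 of 20 higher (adjusted p = 7.2e-06), both with adjusted p = 0.565 with an estimated correlation, including GRIN1 at 245 against 24.8 CPM, SCN1A at 9.90 against 0.847 CPM and SV2B at 15.3 against 1.29 CPM. The cell cycle list had 24 of 25 lower (adjusted p = 1.91e-15), with CDC20 at 19.1 against 169 CPM, the neural progenitor list 13 of 22 lower and 1 higher (adjusted p = 2.22e-05), and the cholesterol list 3 of 18 lower (adjusted p = 0.00233), each with adjusted p = 0.565 with an estimated correlation. The interferon response list had 9 of 17 higher (adjusted p = 0.0491; adjusted p = 0.644 with an estimated correlation), with IFIT2 at 8.31 against 2.05 CPM. The dopaminergic list had 7 of 18 higher and 2 lower (adjusted p = 0.205). The collagen-binding proteoglycan gene DCN was at 46.5 against 1.62 CPM, while the mesenchymal list had 5 of 19 higher and 1 lower (adjusted p = 0.476). Counts adjusted over the list alone were the same for these lists.

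EN2 was called lower in DN than in CN (log2 fold change -2.50 ± 1.06, adjusted p = 0.0484) at means of 5.77 ± 2.47 and 32.7 ± 90.0 CPM, with CN replicates 17 and 20 at 310 and 247 CPM, and was higher in DN with the replicate block (log2 fold change 1.29, adjusted p = 0.0143). Lines 17 and 20 had no DN RNA library. With flowcell as a term the CN level again rests on 1 library. The log2 fold change of TH in DN against CN then went from 1.63 ± 0.46 to -0.24 ± 0.96 (± SE), while that of S100B went from 3.55 ± 0.58 to 5.24 ± 2.30 and of SHH from 2.44 ± 0.69 to 5.51 ± 2.78. In a test against the fold threshold EN1, EN2, FOXA2, IFIT2, SHH and TH were not called.

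Between DN and GA, 556 genes were higher and 633 lower in DN. ASCL1 and DLX2 were lower in DN, at 39.2 ± 10.8 against 548 ± 290 CPM and 12.8 ± 17 against 333 ± 153 CPM (n = 8 and 8; adjusted p = 1.07e-14 and 0.000559), as were DLX1, GAD1 and GAD2, at 15.7, 36.1 and 20.95 CPM against 218, 125 and 127 CPM. The astrocyte-enriched genes MLC1, BCAN and SLC1A3 were higher in DN, at 553, 259 and 229 CPM against 27.01, 16.8 and 35.5 CPM, as were SHH (322 against 22.9 CPM), FOXA1 (192 against 14.3 CPM), TFPI2 (206 against 5.76 CPM) and BHLHE41 (112 against 6.23 CPM). TH was lower in DN than in GA, at 20.2 ± 7.04 against 70.3 ± 64.3 CPM (log2 fold change -1.80 ± 0.57, adjusted p = 0.0253), and lost its call without the 6 libraries of CN, DN and GA with over 16000 genes detected (log2 fold change -1.59, adjusted p = 0.0797), and also where only the 4 of CN and DN among them were left out (-1.62, adjusted p = 0.0515). NR4A2 was at 12.4 and 21.7 CPM and not called (adjusted p = 0.264). It was called lower in DN without the 3 GA libraries of the other code series (log2 fold change -1.35, adjusted p = 0.0382). With flowcell as a term it was called too (-1.36, adjusted p = 0.0338). That term sets the same 3 libraries apart, so these fits are nearly the same check. ANKRD1 and NPPB, both known from heart muscle, were among the 8 largest falls, at 0.201 and 0.114 CPM in DN against 25.0 and 13.8 CPM. SST was lower, at 17.01 against 114 CPM. Both TH and SST were split within GA. In the 3 libraries of the other code series they were at 6.81 to 16.7 and 3.29 to 30.9 CPM. In the other 5 they were at 34.4 to 173 and 61.2 to 438 CPM.

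The astrocyte list had 7 of 16 members higher in DN than in GA (adjusted p = 8.86e-08; adjusted p = 0.136 with an estimated correlation), and AQP4 was at 17.2 against 1.85 CPM, with DN replicate 12 at 104 CPM and the other DN libraries at or below 9.79 CPM. With only the lines found in all 5 groups AQP4 and FOXA1 lost their calls (adjusted p = 0.276 and 0.0759), with their log2 fold changes going from 3.20 to 1.149 and from 3.74 to 3.04. GAD1 lost its call without the libraries with conflicting labels (log2 fold change -1.76 against -1.79, adjusted p = 0.058). The GABAergic list had 10 of 19 lower (adjusted p = 2.18e-07; adjusted p = 0.169 with an estimated correlation) and 13 adjusted over the list alone. The mesenchymal list had 9 of 19 lower and 3 higher (adjusted p = 0.0125; adjusted p = 0.671 with an estimated correlation), with COL6A3 at 4.26 against 48.3 CPM and DCN at 46.5 against 1.86 CPM, and 11 lower adjusted over the list alone. The HOX list had 8 of 16 lower, 11 adjusted over the list alone (adjusted p = 0.0102; adjusted p = 0.671 with an estimated correlation). HOXB5 and HOXB8 were called lower in DN, and both calls were lost with the replicate block (log2 fold changes -3.29 and -2.88 against -5.79 and -5.57, adjusted p = 0.151 and 0.141) and without the 3 GA libraries of the other code series (log2 fold changes -0.66 and 0.09). The neural progenitor list had 4 of 22 higher (adjusted p = 0.000531), the Hedgehog list 6 of 13 higher and 2 lower (adjusted p = 0.0107), the interferon list 3 of 17 higher (adjusted p = 0.00286) and the p53 and integrated stress response list 1 of 18 higher (adjusted p = 0.0304), each with adjusted p = 0.665 with an estimated correlation. The immediate early list had 8 of 23 lower and 1 higher (adjusted p = 0.041; adjusted p = 0.665 with an estimated correlation), and the pan-neuronal list 3 of 23 lower (adjusted p = 0.0304; adjusted p = 0.756 with an estimated correlation).

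For DN against GA the glycolysis and hypoxia list had 0 of 19 members called and was called as a list (adjusted p = 0.0138; adjusted p = 0.665 with an estimated correlation, and 0.0605 with the replicate block). The synaptic vesicle, forebrain patterning, mesoderm and endoderm, and glutamatergic lists were not called (adjusted p = 0.208, 0.52, 0.164 and 0.489) and were called with the replicate block (adjusted p = 0.00502, 0.0146, 0.034 and 0.0452). FOXA2, at 59.7 against 4.81 CPM, was called (adjusted p = 0.0442) and lost in 8 alternatives, with adjusted p from 0.0646 to 0.375 at log2 fold changes of 2.96 to 3.64, against 3.62. Fitted on the GA and DN libraries alone, 268 genes were higher and 199 lower, and TH, FOXA1, AQP4, SST, COL6A3 and HOXB5 were among the named genes no longer called, at log2 fold changes of -1.77, 3.75, 3.20, -2.70, -3.48 and -5.84 against -1.80, 3.74, 3.20, -2.74, -3.49 and -5.79. In a test against the fold threshold AQP4, COL6A3, DLX1, FOXA1, GAD1, GAD2, HOXB8, SHH, SST and TH were not called.

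Of the 27 lists, 8 were called in no comparison of the planned fit. They were the dopaminergic and midbrain floor plate, forebrain patterning and neural crest lists, with lowest adjusted p of 0.055, 0.283 and 0.406, the oligodendrocyte lineage, choroid plexus and ependymal, microglia and blood (1 member tested) and neuronal and progenitor BAF subunit lists, with lowest adjusted p of 0.446, 0.119, 0.197 and 0.0734, and the mesoderm and endoderm list, with 0.143.

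VPS45 (ENSG00000136631.13, chromosome 1, 150067279 to 150145329), a vesicle sorting gene, was at 8.53 ± 2.06 CPM in iPSC, 10.4 ± 1.10 in NPC, 16.5 ± 3.41 in CN, 17.7 ± 4.57 in GA and 17.3 ± 1.32 in DN. Against NPC it was higher by 0.66 ± 0.13, 0.76 ± 0.15 and 0.74 ± 0.15 on the log2 scale in CN, GA and DN (adjusted p = 6.05e-05, 1.91e-05 and 3.4e-05), which was below the fold needed for a call. With flowcell as a term, where the CN level rests on 1 library, the change in CN was 0.51 ± 0.28.

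The lists of open regions held 336835 entries for iPSC, 256085 for NPC, 256947 for CN, 278416 for GA and 281210 for DN, all on autosomes of hg38. They had no replicates. Median widths were 555, 232, 270, 531 and 506 bp. Of GA entries, 67.5% were overlapped by DN entries, and 68.0% of DN entries by GA entries. For NPC and CN the shares were 61.4% and 61.1%. The smallest share was that of iPSC entries overlapped by NPC entries, at 34.3%. The 95% exact binomial intervals lay within 0.2 percentage points of each of these shares and covered counting only. In the stronger part of each list the order turned, with 75.9% and 76.7% for NPC and CN and 72.2% and 72.8% for GA and DN. Entries found in 1 list made up 43.2% of the iPSC list, 22.1% of NPC, 16.8% of CN, 21.6% of GA and 14.2% of DN, and 22.5% to 30.6% of each list was overlapped in all 5. Of the entries in all 5 lists 15.7% to 16.6% lay within 1 kb of a transcription start, against 0.37% to 0.80% of those in 1 list.

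**Figure D3:**
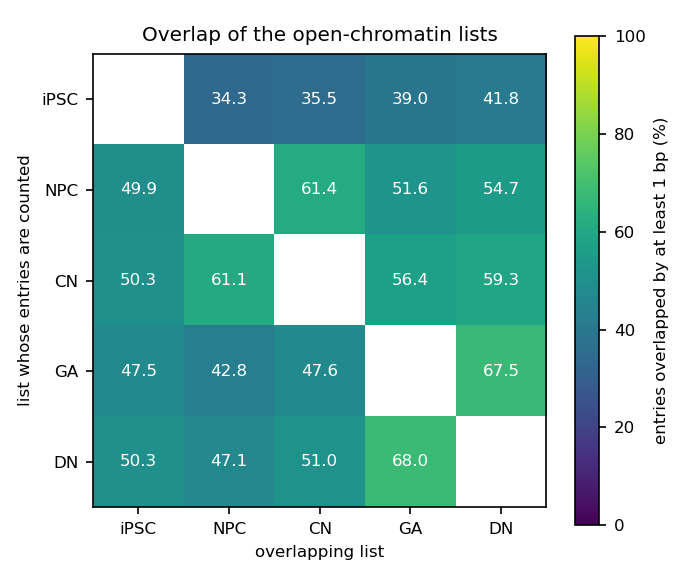
Percent of the entries of each open-chromatin list (rows) that were overlapped by at least 1 bp by an entry of another list (columns). The darkest cell off the diagonal is iPSC entries overlapped by NPC entries, at 34.3%, and the brightest is DN entries overlapped by GA entries, at 68.0%.

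Most called genes had an entry within 1 kb of their start in the cell type where they were higher, 84.5% over the 7 comparisons, but genes not called had one about as often. For genes higher in GA than in NPC, 86.0% had a GA entry and 80.0% an NPC entry, and 7.5% had only the GA entry against 1.5% with only the NPC entry. Of genes not called in that comparison, 87.4% had a GA entry and 85.1% an NPC entry, 3.7% only the GA entry and 1.5% only the NPC entry. For genes lower in NPC than in iPSC, 14.8% had only an iPSC entry and 1.2% only an NPC entry. For genes higher in NPC than in iPSC, however, 8.5% had only an iPSC entry and 2.2% only an NPC entry, against 5.3% and 1.2% of genes not called. At POU5F1 an entry within 1 kb of the outermost annotated start (chromosome 6, 31180761 to 31180880) was listed in iPSC alone. Starts of other transcripts of a gene were not looked at, so this entry need not mark the promoter in use. At FOXA2 and at SHH an entry was listed in iPSC, CN, GA and DN and not in NPC, and at TH in NPC, CN, GA and DN and not in iPSC. The DLX2 start had an entry in all 5 lists.

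Distal entries, from 1 to 50 kb around the start of called genes, were counted against 10000 random gene sets matched on expression. The smallest possible p is 0.0001. Genes were drawn singly, although neighbouring genes can share entries, and the lists had no replicates. The p thus covers the draw of genes only, not the spread between libraries, and may be too small. NPC-only entries were 1.18 times as frequent around genes higher in NPC than in iPSC, and iPSC-only entries 1.16 times around genes lower in NPC (adjusted permutation p = 0.000168 for both). CN-only entries were 1.28 times as frequent around genes higher in CN than in NPC, but also 1.29 times around genes lower in CN. GA-only entries were 1.149 times as frequent around genes higher in GA than in NPC, and DN-only entries 1.047 times around genes higher in DN than in NPC. NPC-only entries were 1.06 and 1.07 times as frequent around genes lower in GA and in DN than in NPC. Around genes lower in DN than in GA, GA-only entries were 1.18 times and DN-only entries 0.877 times as frequent. Entries of the higher cell type were not called for genes higher in DN than in GA (1.03, adjusted p = 0.463), lower in CN than in NPC (1.04, adjusted p = 0.188), and lower in GA or in DN than in CN (1.02 for both, adjusted p = 0.454 and 0.421). CN-only entries were 1.29 and 1.25 times as frequent around genes higher in GA and in DN than in CN, that is, around genes lower in CN. Around the same genes GA-only entries were 1.11 times (adjusted p = 0.000168) and DN-only entries 1.04 times as frequent (adjusted p = 0.00159). Entries present in both lists were 1.04 to 1.18 times as frequent around called genes in every comparison and direction.

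**Figure D4:**
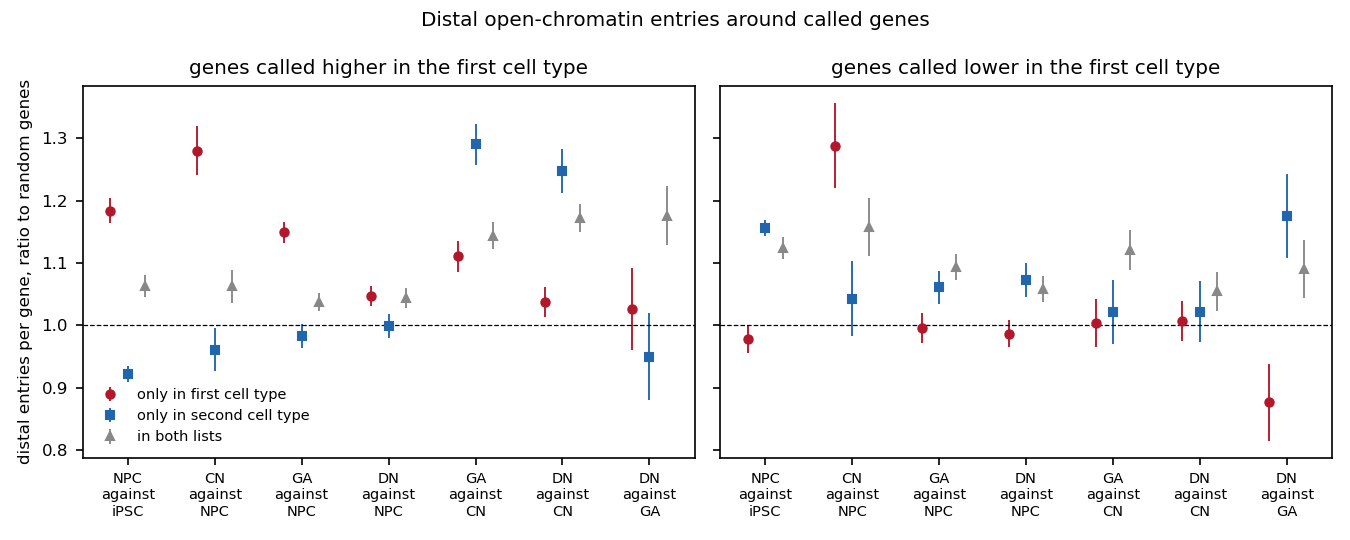
Distal open-chromatin entries per gene around called genes, as a ratio to random gene sets matched on expression (vertical axis), for the 7 comparisons (horizontal axis). Red circles are entries only in the list of the cell type named before "against", blue squares those only in the other list and grey triangles those in both; bars are 2 SD of the random sets. CN-only entries stand at 1.29 around genes higher in GA than in CN.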

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

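The tests chosen only after the result was seen were flowcell as a term and the count of HOX genes still called without the 3 GA libraries of another code series, although the fit without those libraries was planned; the test of other splits of the libraries was planned too, but the outcomes that would decide it were written after its counts were seen.

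In each comparison the real split of the libraries called more genes than all 40 random splits, 1 of 41 with the real one included. A random split puts libraries of both cell types in each part, which widens the spread within it. Such splits thus tend to call few genes. The test says only that the compared groups differ in some way, whatever the cause. In NPC against iPSC 6940 genes were called, and at most 436 in the random splits. The real and highest random counts were 2600 and 1872 in CN against NPC, 6745 and 1959 in GA against NPC, 6557 and 4210 in DN against NPC, 3902 and 758 in GA against CN, 3580 and 1197 in DN against CN, and 1189 and 788 in DN against GA. Random splits ignore that the libraries are paired by line, so the real split was also set against 30 splits per comparison that part every line's pair; 15 had been drawn at first, and 15 more were added after those were seen. The real split called more genes than all of them, 1 of 31 with the real one included. Their highest counts were 4747, 1819, 4040, 4358, 2678 and 2595 in the order of the report, and in DN against GA the highest lay under that of the random splits. The median of the random splits was 0 to 2 genes, so a few splits called many genes. How many real labels each split kept was not recorded. These counts thus do not tell the cell types from other structure among the libraries.

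CN differed from NPC in 2600 genes while 17 of the 18 CN libraries were on another flowcell than the NPC libraries. If the flowcell were the cause, the CN library on the NPC flowcell would show at most 0.25 of the median change of the others, and if not, at least 0.75. It showed 0.725, with a median change of 1.054 against 1.455 (0.96 to 1.82 in the other CN libraries) over the 2660 genes called without it, and 89.8% of these genes moved the same way. With flowcell as a term the median change over the 2600 called genes went from 1.64 to 1.20 and the median SE from 0.37 to 0.82, with 90% of the genes still moving the same way. Both the share and this fit rest on 1 CN library, so flowcell and cell type cannot be told apart for these genes, and the differentiation itself stays open, untested apart from this.

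Of 16 HOX genes, 7 were called higher and 1 lower in GA than in NPC, and the list was not called (adjusted p = 0.746). Of the 7, 1 was still called without the 3 GA libraries of another code series, HOXA5, so the high values of those libraries are a candidate explanation for the other 6. These libraries also differ in flowcell and line. If the line were the cause, the CN libraries of the same 3 lines would be the 3 highest of the 18 in the called HOX genes; 1 of the 3 lines was, which decides nothing.

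CN-only entries were more frequent around genes higher in GA than in CN, at 1.29 times the random sets, although these genes were lower in CN. Gene length does not account for it, since matching on length left the ratio at 1.288 ± 0.02 (SD of the random sets). Density of open chromatin does not account for all of it, since matching on the entries of the combined list left 1.209 ± 0.017. Weak entries do not account for all of it either, since with only CN entries at or over the median score the ratio was 1.211 ± 0.032, above the bound set beforehand by more than 1 SD and less than 2 SD. A smaller part for density or weak entries stays open, as do both together, and no biological explanation was tested.

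In 247 tests of groups of 8 libraries, 47 had a highest library set apart from the other 7 by more than Dixon's 95% critical value of 0.526. That value assumes a normal spread, while CPM were not transformed and the genes were picked after their values were seen. The number expected by chance is thus not known. Of these, SYNPR and DLX6 in NPC rest on 1 count in the group, which sets a library apart by construction, so they say nothing. Leaving out the 5 tests with at most 3 counts, 45 of 242 remain. The value of the library set apart is given with the highest of the others, in CPM. GA replicate 16 stood apart for 8 genes: FOXA2 (28.19, others to 8.77), SHH (91.22, to 38.9), HES5 (86.55, to 18), SOX3 (497.9, to 154), SALL4 (26.8, to 9.86), MCM2 (157.5, to 61.5), NEUROG1 (8.851, to 3.51) and NEUROG2 (30.82, to 14.6). GA replicate 05 stood apart for GFAP (551.3, to 7.2), HOXA5 (469.2, to 218) and HOXB8 (805.3, to 72.2), GA replicate 04 for TFPI2 (21.36, to 7.75), GA replicate 08 for SCN1A (20.55, to 10) and GA replicate 18 for SST (437.7, to 179).

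DN replicate 12 stood apart for AQP4 (103.9, to 9.79), GFAP (989.4, to 246), COL6A3 (23.63, to 5.75) and TFPI2 (570.5, to 266). DN replicate 09 did so for GRIN1 (483.1, to 263), NR4A2 (30.26, to 12.3), HOXB5 (11.12, to 1.61) and HOXB8 (14.82, to 2.37), DN replicate 16 for DLX2 (52.18, to 17.4) and GLI1 (1.373, to 0.699), and DN replicate 11 for SHH (795.1, to 431).

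NPC replicate 12 stood apart for COL1A1 (728.2, to 65.8), COL3A1 (337.0, to 71.9), EN1 (7.924, to 0.893) and S100B (2.247, to 0.546). NPC replicate 09 did so for HOXB4 (78.62, to 28.5), HOXB5 (7.811, to 0.706), HOXB8 (35.35, to 5.14) and FOXG1 (0.4111, to 0.101), NPC replicate 16 for FOXA2 (11.96, to 3.69), SHH (49.95, to 18.2), PRDM14 (0.2991, to 0.118) and SYNPR (0.0997, to 0), NPC replicate 18 for HES5 (1109, to 716), EGR3 (30.81, to 16.9) and DLX6 (0.08929, to 0), and NPC replicate 21 for OTX2 (6.047, to 1.52), PLK1 (230.3, to 195) and PMP2 (0.4031, to 0.118). The total count was 12705047 in NPC replicate 18, with the others at up to 10450157. In iPSC, replicate 21 stood apart for STMN2 (8.255, to 2.25), PAX6 (1.809, to 0.857) and HOXB3 (0.7916, to 0.209).

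In the 5 neural progenitor libraries put in no group, whose titles carry a prefix that points to VPS45 itself, VPS45 was at 13.86, 18.82, 16.43, 16.22 and 17.53 CPM, above the 8.87 to 11.6 CPM of the NPC libraries. What was done to these cells is not given, so their VPS45 level cannot be read as that of untreated progenitors.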

How the results depend on the processing

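Flowcell as a term, the fits without 6 libraries with many genes detected and without the 4 of CN and DN among them, lists without entries over 10 kb and equal numbers of entries in the distal test were chosen after the data were seen; the other alternatives were planned. Of 1460 results of single genes, 954 kept direction and call in all alternatives run for single genes, as did 96 of 189 list tests and 0 of 14 counts of called genes. Per alternative, 1460 of 1460 gene results were the same with a stricter low-count filter, 1445 with relative log expression scaling, 1442 with upper-quartile scaling, 1419 with DESeq2, 1418 without a filter, 1357 with the replicate block and 1148 with flowcell as a term. VPS45 kept its side of the call in each of these; having no fold threshold was tried for counts only, and by its adjusted p alone VPS45 would then be called in CN, GA and DN against NPC. No scaling moved the median of all genes by over 0.1 or the share of higher calls by over 10 points from the planned analysis. Unless a cause is named, the cause was not tested.

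Counts moved over 1.5 times as follows. With no low-count filter more genes were tested, and NPC against iPSC had 5072 lower, GA against NPC 6620 higher, GA against CN 5137 higher and DN against CN 3887 higher. Tested against the fold threshold itself, a stricter rule, NPC against iPSC had 2373 higher, CN against NPC 782 higher and 120 lower, GA against NPC 2810 and 1369, DN against NPC 2637 and 1393, GA against CN 1203 and 351, DN against CN 935 and 540, and DN against GA 82 and 98. With no fold threshold, a looser rule, the counts were 5584 and 5284 in NPC against iPSC, 3850 and 3057 in CN against NPC, 4970 lower in GA against NPC, 5035 lower in DN against NPC, 4754 and 4104 in GA against CN, 4355 and 4099 in DN against CN, and 1280 and 1327 in DN against GA. With flowcell as a term CN against NPC had 308 higher and 43 lower, GA against CN 1677 higher and DN against CN 943 higher. Fitted on the compared libraries alone, DN against GA had 268 higher and 199 lower. List calls fell from 58 to 4 with the estimated correlation.

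Log2 fold changes that reversed with flowcell as a term were, in CN against NPC, FOXG1 -2.68, GRIN2A -0.604, IFIT2 -0.75, NKX6-2 -0.009, PAX5 -2.09, SHH -0.826 and SYN2 -1.23; in GA against CN, EN2 2.39, ESRP1 -1.13, HHIP 0.912, MIXL1 -1.81, NEUROD2 -0.321 and SLC17A7 -0.356; in DN against CN, EN2 2.33, FOXG1 1.54, TH -0.239 and ZSCAN10 -0.15; in GA against NPC, HOXB8 -1.35; and in DN against GA, GDF3 1.504, HOXB8 0.071 and NEUROD2 4.69 (adjusted p = 0.000201). Without the 3 GA libraries of the other code series, HOXB8 was at -1.30 in GA against NPC, -0.318 in GA against CN and 0.094 in DN against GA, NEUROD2 at -0.57 in GA against CN and 4.688 (adjusted p = 1.02e-05) in DN against GA, and GDF3 at 1.504 in DN against GA. In DN against GA the cell cycle list changed direction, with adjusted p = 0.0317 without those libraries and 0.0356 with flowcell as a term. With only lines found in all groups, EN2 was at 1.76 in GA against CN and 1.68 in DN against CN, and NEUROD2 at 4.43 in DN against GA (adjusted p = 7.53e-07). With DESeq2, EN2 was at 0.455 in GA against CN and 1.63 in DN against CN. In the comparisons with CN, the fit with flowcell as a term rests on 1 CN library. The term also gives the 3 GA libraries of the other code series a level of their own. The GA level then rests on the other 5. For GA against NPC and DN against GA it is thus nearly the same check as leaving those 3 out.

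With the replicate block, EN2 was at 0.794 in GA against CN and 1.29 in DN against CN, and LHX2 at 1.92, NEUROD2 at 4.21 and SIX3 at 1.66 in DN against GA, where these 3 were not called without the block and were called higher in DN with it (adjusted p = 0.0342, 5.2e-05 and 0.0314). The block moved no count of called genes over 1.5 times: the counts with it were 3677 and 3459, 2045 and 965, 4073 and 2765, 4012 and 2670, 2486 and 1269, 2203 and 1197, and 588 and 609. Of the lists, 13 were called only with it and 1 only without it, 70 calls against 58. Of the calls that the report gives for a comparison, it changed no other than those named there.

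The share of entries shared, a mean over 20 ordered pairs of lists that ran from 34.3% to 68.0%, was 50.85%. It was 57.25% in the stronger part of each list, 28.65% with 50% reciprocal overlap, 51.52% with equal list sizes and 50.54% without entries over 10 kb. A change was counted from 0.2 points, an arbitrary bound. The mean number of entries was 142934 in the stronger part against 281899, by construction. Promoter entries rose from 84.5% to 88.59% with 2 kb, a wider window. With a 500 bp gap, NPC-only entries near genes lower in NPC than in iPSC stood at 0.957 and those near genes higher in GA than in NPC at 0.973, both then called, and DN-only entries near genes higher in DN than in CN at 1.016, no longer called. With 100 kb, NPC-only entries near genes higher in DN than in NPC stood at 1.023 against 0.999. The motif alternatives were not run.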

Other observations

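The comparisons by line described here were chosen after the values were seen. Several genes of regional identity were highest in libraries of the same line across cell types. In line 09, HOXB5 and HOXB8 were the highest of 8 in NPC (7.811 and 35.35 CPM) and in DN (11.12 and 14.82 CPM), and HOXB4 was the highest in NPC (78.62 CPM). HOXB5 and HOXB8 were also highest of 18 in CN (10.72 and 24.28 CPM), but 4th of 8 in GA (10.09 and 7.043 CPM). In line 16, FOXA2 was the highest of its group in NPC (11.96 CPM), CN (49.28 CPM) and GA (28.19 CPM) and the next after the highest in DN (118.1 CPM), but 5th of 8 in iPSC. Genes and lines were picked for their high values, and no test of a line effect was run on them.

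Some lists had many called members without passing the list test. The interferon response list had 9 of 17 members higher in DN than in NPC (adjusted p = 0.259), the choroid plexus and ependymal list 7 of 9 higher in GA than in NPC (adjusted p = 0.393) and the mesoderm and endoderm list 5 of 7 higher in DN than in NPC (adjusted p = 0.19). The HOX list had 9 of 16 higher in GA than in CN (adjusted p = 0.195).

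GA libraries of the other code series differed from the other 5 beyond HOX genes. TH was at 6.81 to 16.7 CPM in the 3 and at 34.4 to 173 CPM in the other 5, SST at 3.29 to 30.9 and 61.2 to 438 CPM, and VPS45 at 21.6 to 23.2 and 13.04 to 19.7 CPM.

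In the 5 libraries of no group, labelled as neural progenitors, the progenitor gene SOX1 was at 290 to 461 CPM (median 311), PAX6 at 231 to 365 CPM (median 314), HES5 at 170 to 384 CPM (median 325), LIN28A at 534 to 982 CPM (median 675), the proliferation gene MKI67 at 510 to 689 CPM (median 669), STMN2 at 100 to 279 CPM (median 266) and HOXB2 at 108 to 136 CPM (median 116). POU5F1 was at 0 to 0.373 CPM. In NPC, SOX1 ran from 564 to 995 CPM, PAX6 from 54.05 to 196 CPM and MKI67 from 373 to 503 CPM.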
